A study of Mus musculus with 30 samples.

How the data were processed

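RNA sequencing measured NKp46-GFP+ NK cells sorted after skin grafting in 2 models, with 30 libraries in 10 groups of 3. In the B6 model, NKp46iCre/iCre.RosamTmG/mTmG recipients carried m157tg B2m-/- skin for 20 days; in the F1 model, NKp46+/iCre.Rosa+/mTmG recipients carried m157tg B2m+/- skin for 10 days. Each model had CD49b+ cells from blood, spleen and graft and CD49a+ cells from graft and recipient skin. The labels do not say whether libraries with the same number share an animal.

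The deposited table holds signal: values that the authors normalized with DESeq2, per the submitters' processing notes, after Salmon quantification on GRCm38/mm10. Versions, annotation and filters are not given in the sources used here. Only 15.0 to 22.1 percent of low values in a library were whole multiples of the smallest step at a tolerance of 0.1, so whole reads were not recovered. Fractional estimates and factors that differ between genes were not separated as the reason. Of 30616 entries, 30587 were used; 1 had no name, 27 carried symbols turned into dates and 1 held a letter in place of a number. A remark was taken off 1 symbol, 2 list members were found under older symbols (Emr1 and Faim3), and 2 unnamed numeric columns were not used here. Symbols were matched to GENCODE M21 on GRCm38 for 28639 genes, of which 20707 are protein coding, and locations come from that annotation; Ccdc37, Cd244 and D8Ertd82e had no match there.

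Sums of the signal ran from 3502576 to 5717946 in the 12 circulating libraries and from 1529124 to 3988756 in the 18 skin libraries. Of these, 12 satellite-like predicted genes such as Gm10800 held 78.9 to 85.1 percent in circulating and 18.6 to 78.3 percent in skin libraries. Outside them the sums were 706464 to 913405 and 866215 to 1670043, with 8129 to 8620 and 8402 to 11300 genes at 10 or more. Mitochondrial genes held 1.33 to 1.82 percent of that rest in circulating and 0.454 to 9.50 percent in skin libraries. Replicates correlated with r of 0.796 to 0.897 in circulating and 0.41 to 0.739 in skin groups.

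Gene tests used limma 3.58.1 (R 4.3.3) on log2 of the signal plus 1, with 1 mean per group over all 30 libraries, eBayes with trend and robust settings, and Benjamini-Hochberg adjustment with a threshold of 0.05. The 16045 genes with a signal of at least 10 in at least 3 libraries were tested, 14167 of them protein coding. Comparisons were graft CD49b+ against spleen, graft CD49a+ against graft CD49b+ and against recipient skin, spleen against blood, and recipient skin against spleen, in each model, and the difference between the models for the first 3. Folds are 2 to the power of the fitted change, and errors of means are SD of the signal. Data were prepared with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3 and drawn with matplotlib 3.10.9.

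Gene lists were tested with camera on the same fit, with its preset correlation of 0.01 and with an estimated correlation, adjusted over the lists of a comparison. The 29 lists with at least 3 tested members were tissue residency, egress and recirculation, NK cell maturation, cytotoxic effector genes, cytokine and chemokine ligands, inhibitory receptors and chronic stimulation, NK receptors, cytokine receptors, chemokine receptors, lymphocyte transcription factors, cell cycle, type I interferon response, TGF-beta response, glycolysis and hypoxia, oxidative phosphorylation, lipid handling, immediate early and dissociation stress, ribosomal proteins, and markers of keratinocytes, fibroblasts, endothelium, macrophages and monocytes, dendritic cells and MHC class II, neutrophils, mast cells and basophils, T cells, B cells, ILC2 and ILC3, and erythroid cells and platelets. Named genes were, per model, the 5 largest rises and falls with an adjusted p under 0.05, a mean of at least 50 in the higher group and no overlap between the groups (3 and 3 for spleen against blood and recipient skin against spleen), without predicted genes, antigen receptor segments, mitochondrial genes and the sort markers Itga1, Itga2 and Ncr1. Up to 3 members of each list with the smallest p, and the most abundant member of each marker list, were added; a few genes that this rule names are not reported here. Groups, comparisons, tests, lists, the naming rule and 13 alternatives were set before the data were examined.

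The alternative settings changed the pseudocount, the filter (2 ways), the scaling (quantile, or the same total in each library, which took the place of TMM because the values are not counts), library weights, a block for the library number, the libraries sharing the spread, the reference tissue, single libraries and the correlation of camera; tests on recovered reads could not be run. A further 4 were added after the data were seen: scaling to 20 pan-leukocyte transcripts (the leukocyte scale), the same total without the satellite-like genes, the 18 skin libraries alone, and leaving out the 8 skin libraries more than 2 log2 units below the circulating pan-leukocyte level. Libraries with the same number were not paired. Their deviations from the group means correlated above 0.1 for each number only for graft against recipient CD49a+ cells in B6 (r = 0.14, 0.40 and 0.15).

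The fit was tested on 10 simulated sets of independent genes with 200 changed in each, with the spread of the circulating and skin libraries and the B6 comparisons. For graft CD49b+ against spleen, 0.3, 7.8 and 29.0 percent of 2-, 4- and 8-fold changes were recovered and 8.1 percent of calls were false. They were 1.0, 12.8 and 35.4 with 44.3 percent false for graft CD49a+ against CD49b+, and 1.7, 15.1 and 36.6 with 42.4 for graft CD49a+ against recipient skin. They were 0, 4.8 and 28.4 with 15.4 for spleen against blood, and 0.5, 8.8 and 29.3 with 5.3 for recipient skin against spleen. With the egress list shifted by -2, camera gave it an adjusted p of 1.56e-12 and called 0 of 27 other lists, which leaves its preset correlation untested. Relative list scores had 100000 permutations (seed 7) and other splits of the libraries at most 100 (seed 20).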

Results

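Natural killer (NK) cells were compared between blood, spleen, grafted skin and the recipient's own skin in 2 graft models with 3 libraries per group. In the B6 model, C57BL/6 recipients were studied at day 20 after a B2m-deficient graft carrying m157, and in the F1 model, F1 recipients were studied at day 10 after an m157 graft with 1 B2m copy. Itga1, which encodes CD49a, had a mean ± SD of 72.8 ± 45.9 in B6 recipient skin CD49a+ cells and 8.19 ± 4.55 in B6 spleen, and 31.4 ± 24.1 and 6.73 ± 1.01 in F1. Itga2, which encodes CD49b, was at 47.0 ± 6.12 in B6 spleen and 13.2 ± 3.59 in B6 recipient skin CD49a+ cells, and at 40.0 ± 5.39 and 7.02 ± 6.92 in F1. Within the graft, CD49a+ and CD49b+ cells had Itga1 at 53.4 ± 55.3 and 23.4 ± 17.5 in B6 and 40.5 ± 17.0 and 11.8 ± 9.35 in F1, and Itga2 at 8.30 ± 4.25 and 16.9 ± 4.50 in B6 and 6.13 ± 0.614 and 13.5 ± 4.12 in F1. Single B6 graft libraries overlapped, with Itga1 at 12 in CD49a library 1 and 43.4 in CD49b library 3. Ncr1, which encodes NKp46, was at 366 ± 36.4 in B6 spleen, 48.7 ± 6.70 in graft CD49b+ cells, 14.7 ± 7.73 in graft CD49a+ cells and 18.3 ± 8.56 in recipient skin. The F1 values of Ncr1 were 870 ± 7.76, 66.3 ± 13.2, 52.7 ± 24.7 and 28.5 ± 8.07 in the same order.

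The skin libraries held fewer leukocyte transcripts than the circulating ones. As a percentage of the circulating libraries, the level of 20 pan-leukocyte transcripts such as Ptprc was 55.8 ± 25.4 in B6 graft CD49b+ cells, 31.4 ± 33.4 in B6 graft CD49a+ cells and 30.1 ± 34 in B6 recipient skin. The corresponding F1 values were 39.6 ± 3.03, 28.5 ± 10.7 and 19.4 ± 9.41, against 91.9 to 112 in the 12 circulating libraries. Transcripts of other cells were prominent in single skin libraries: the erythroid Hbb-bs reached 11464 and the neutrophil S100a9 4925 in F1 graft CD49a library 2, and the macrophage Lyz2 reached 5604 in F1 recipient skin library 1. The collagen gene Col1a1 was at 224 ± 350 in B6 graft CD49b+ cells and 242 ± 229 in B6 graft CD49a+ cells. The B6 spleen libraries carried the B cell transcript Cd79a at 54.8 ± 45.1, S100a9 at 92.1 ± 80.0 and Lyz2 at 66.7 ± 40.3, against 2.09, 0 and 1.56 in F1 spleen.

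**Figure D1:**
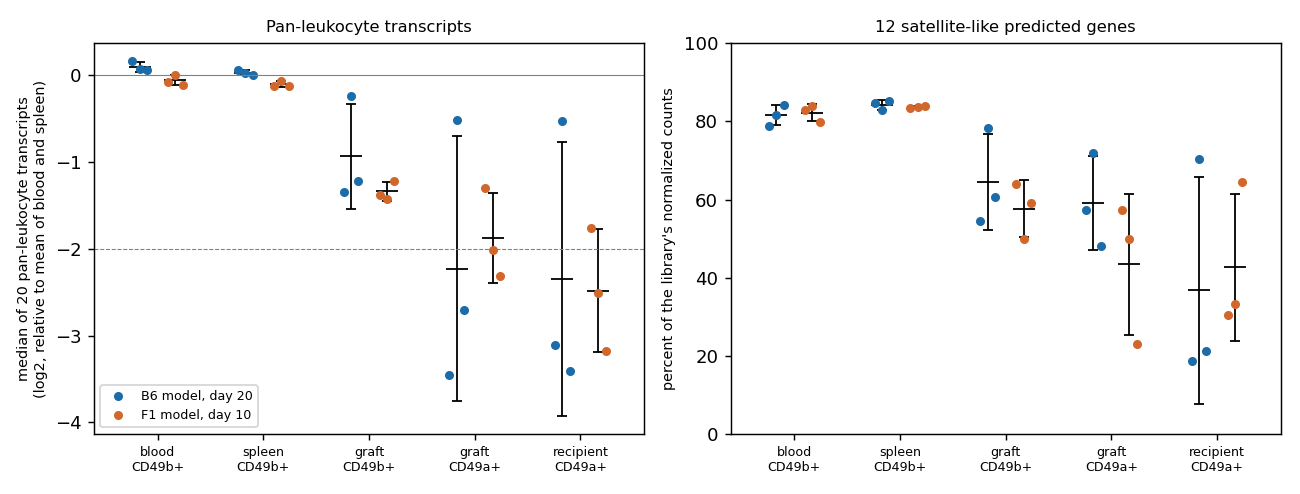
Level of 20 pan-leukocyte transcripts relative to the circulating libraries (log2, dashed line at -2) and share of signal in 12 satellite-like predicted genes, for each of 30 libraries. Blue marks the B6 model, orange the F1 model, and bars mean ± SD.

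In CD49b+ cells of the graft, receptors that guide NK cells out of tissue were lower than in spleen. S1pr5, the sphingosine-1-phosphate receptor of NK cell egress (GRCm38 chromosome 9, 21242912 to 21248443), fell by 5.34 ± 0.95 on the log2 scale (mean ± SE) in B6, 40.5-fold, from 323 ± 21 to 8.55 ± 6.71 (adjusted p = 0.00458). In F1 it fell by 6.25 ± 0.95, 76.1-fold, from 287 ± 26.7 to 4.43 ± 4.40 (adjusted p = 0.000407). Cx3cr1, the fractalkine receptor, fell 11.3-fold in B6 (adjusted p = 0.00658) and 9.29-fold in F1 (adjusted p = 0.00317). Ccr7, the receptor that brings lymphocytes to lymph nodes, rose 59.9-fold in F1, from 1.91 ± 3.31 to 114 ± 28.0 (adjusted p = 0.000407), and was at 62.3 ± 29.9 against 13.0 ± 11.2 in B6 (adjusted p = 0.119). Of 13 genes of egress and recirculation, 3 fell and 0 rose in B6 (limma; 1 rose and 7 fell when adjusted over the list alone), and 4 fell and 1 rose in F1 (4 and 1 over the list alone). The medians were -2.0 and -1.94, with adjusted p = 6.59e-07 and 4.99e-05, and 0.000375 and 0.00329 with an estimated correlation. The medians on the leukocyte scale stayed negative, at -1.04 and -0.71, while Cx3cr1 did not pass in either model (adjusted p = 0.0655 and 0.0591) and S1pr5 passed only in F1 (0.0894 in B6 and 0.0128 in F1).

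Genes linked to tissue residency were higher in the same graft cells. Nr4a1 and Nr4a2, nuclear receptors induced by stimulation, rose 21.8-fold and 21.3-fold in B6, to 517 ± 142 and 284 ± 206 (adjusted p = 0.00274 for each). Litaf, an endosomal protein gene, rose 10.6-fold in B6 to 458 ± 201 (adjusted p = 0.0031) and 14.8-fold in F1 to 436 ± 94.2 (adjusted p = 0.000252). In F1, Nr4a2 rose 6.75-fold (adjusted p = 0.013), and Nr4a1 was at 80.2 ± 9.92 against 23.4 ± 5.89 (adjusted p = 0.101). Of 23 residency genes, 7 rose and 0 fell in B6 (12 and 0 over the list alone; median 2.06, adjusted p = 6.59e-07), and 6 rose and 0 fell in F1 (9 and 0 over the list alone; median 1.41, adjusted p = 0.0111). The adjusted p was 0.218 and 0.54 with an estimated correlation, and 0.000103 and 0.00505 on the leukocyte scale. Of the 23 genes, 7 were set apart by hand as immediate early genes (Nr4a1, Nr4a2, Rgs1, Rgs2, Sik1, Cd69 and Skil), of which 5 rose in each model. The other 16 had medians of 1.90 in B6 (p = 0.000198, and 0.0775 with an estimated correlation) and 0.85 in F1 (p = 0.108, and 0.431).

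Inhibitory receptors and genes of chronic stimulation followed the residency genes. Tigit, an inhibitory receptor, rose 5.56-fold in B6 to 366 ± 152 (adjusted p = 0.00704) and 11.1-fold in F1 to 589 ± 60.1 (adjusted p = 0.000221). Cd274, which encodes PD-L1, rose 4.86-fold and 5.29-fold (adjusted p = 0.0126 and 0.00305), and Nr4a3 rose 13.7-fold and 4.78-fold (adjusted p = 0.00596 and 0.0356). Of 18 members, 4 rose and 0 fell in B6 (4 and 1 over the list alone; median 1.01, adjusted p = 0.0471), and 9 rose and 1 fell in F1 (10 and 2; median 2.27, adjusted p = 0.0147); the adjusted p was 0.697 and 0.54 with an estimated correlation. Of 23 immediate early and dissociation stress genes, 7 rose in B6 (10 over the list alone; median 1.60, adjusted p = 8.59e-06) and 6 in F1 (8 over the list alone; median 0.95, adjusted p = 0.0251), with 0.223 and 0.54 with an estimated correlation. Dusp1, a phosphatase of this list, rose 7.51-fold and 4.57-fold (adjusted p = 0.00431 and 0.00667), and the chaperone Hspa1a rose 59.8-fold in F1 (adjusted p = 0.000804). Of 16 TGF-beta response genes, 3 rose in B6 (4 over the list alone; median 0.99, adjusted p = 0.0471, and 0.218 with an estimated correlation) and 6 in F1 (7 over the list alone; median 1.25, adjusted p = 0.0669). Some of these calls were lost without 1 library. Inhibitory receptors had 1.04 without B6 graft library 2 (0.405) and TGF-beta genes 0.65 without B6 graft library 3 (0.0663). Immediate early genes had 0.92 without F1 spleen library 2 (0.052). The TGF-beta feedback regulator Pmepa1 was listed at 0 in B6 spleen and at 25.9 in the graft (adjusted p = 0.0107).

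NK receptors were lower in the graft CD49b+ cells. Klrb1c, which encodes NK1.1, fell 4.64-fold in F1, from 628 ± 67.5 to 137 ± 35.1 (adjusted p = 0.00957), and was at 345 ± 134 against 912 ± 39.6 in B6 (adjusted p = 0.114). Klrc2, an activating receptor gene, fell 3.61-fold in B6 and 4.27-fold in F1 (adjusted p = 0.0411 and 0.0106). Of 31 members, 1 fell and 0 rose in B6 (1 and 0 over the list alone; median -1.06, adjusted p = 3.98e-06), and 7 fell and 0 rose in F1 (limma; 12 and 1 over the list alone; median -1.62, adjusted p = 1.72e-08), with adjusted p = 0.279 and 0.223 with an estimated correlation. The medians on the leukocyte scale were -0.09 and -0.39, and neither Klrb1c (adjusted p = 0.244 in F1) nor Klrc2 (0.497 and 0.44) passed. Of 14 maturation genes, 1 fell in B6 (4 fell and 2 rose over the list alone; median -1.43, adjusted p = 0.00675, and 0.279 with an estimated correlation) and 2 in F1 (median -0.78, adjusted p = 0.0551). The chymase gene Cma1 fell 6.70-fold in B6 (adjusted p = 0.0172), and Klrg1, an inhibitory receptor of mature cells, fell 6.00-fold in F1 (adjusted p = 0.018); on the leukocyte scale neither passed (0.382 and 0.267). The chemokine gene Ccl5 fell 5.93-fold in F1 from 5806 ± 744 (adjusted p = 0.0325). Of 6 fits without 1 library, Klrc2 (B6) and Ccl5 lost their call in 5, Cma1 in 4 and Klrg1 in 3.

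Single granzyme, metabolic and growth genes of the graft CD49b+ cells also changed. The granzyme gene Gzmc rose by 3.61 ± 1.04 in B6, to 26.9 ± 34.7 (adjusted p = 0.0456), and by 4.13 ± 1.04 in F1, to 25.4 ± 18.4 (adjusted p = 0.0115). Dgat1, an enzyme of triglyceride synthesis, rose 16.7-fold in B6 and 12.4-fold in F1 (adjusted p = 0.00591 and 0.00303). The hexokinase gene Hk2 rose 9.23-fold and 13.7-fold (adjusted p = 0.0187 and 0.00245), and the growth factor gene Vegfa 11.2-fold and 17.4-fold (adjusted p = 0.0198 and 0.00247). Of 6 fits without 1 library, Gzmc and Vegfa lost their B6 call in 5 and Hk2 in 4. Of 33 cell cycle genes, 0 passed in B6 (limma; median 0.26, adjusted p = 0.666), while 2 fell and 1 rose in F1 (7 and 1 over the list alone; median -1.07, adjusted p = 2.05e-05, and 0.17 with an estimated correlation; 0.13 and 5.76e-06 on the leukocyte scale, and 0.61 and 0.518 with blood as the reference). The mitotic kinase gene Plk1 fell 18.2-fold in F1 (adjusted p = 0.0179, and 0.139 on the leukocyte scale). Oxidative phosphorylation and ribosomal protein genes, 0 of 22 and 0 of 24 past the threshold in each model, had medians of -0.22 and -0.40 in B6 and -0.46 and -0.27 in F1. Those 4 medians turned positive on the leukocyte scale and with the same total in each library; their adjusted p ran from 0.0112 to 0.033, and from 0.649 to 0.8 with an estimated correlation. All 4 calls were lost without 1 graft library, at -0.08 and -0.04 without B6 library 1 (0.206 and 0.391) and -0.34 and -0.13 without F1 library 2 (0.0789 and 0.205).

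The remaining gene groups had no list call in graft CD49b+ cells. In B6 and F1 the medians were -0.17 and -0.22 for 18 cytotoxic effector genes (adjusted p = 0.274 and 0.835; mean 0.50 in F1), 0.29 and -0.18 for 17 cytokine and chemokine ligands (0.892 and 0.53; mean 0.16 in F1), and 0.19 and 0.12 for 21 cytokine receptors (0.532 and 0.564). They were 0.70 and 0.79 for 12 chemokine receptors (0.734 and 0.803), 0.29 and 0.25 for 21 lymphocyte transcription factors (0.788 and 0.726), and 0.80 and 0.78 for 28 type I interferon response genes (0.607 and 0.212). Glycolysis and hypoxia genes had 0.21 and 0.29 (25 genes; 0.812 and 0.926), and lipid handling genes 0.56 and -0.03 (20 genes; 0.568 and 0.746; mean 0.35 in F1).

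Markers of other cells moved with these changes. In B6, keratinocyte and fibroblast markers had medians of 3.41 and 3.06 (11 and 12 genes; adjusted p = 0.000663 each, 0.351 each with an estimated correlation), endothelial markers 2.30 (10 genes; 0.0262, and 0.697; 1.55 and 0.274 without graft library 3), neutrophil markers -2.31 (10 genes; 0.00508, and 0.491) and B cell markers -2.77 (10 genes; 8.59e-06, and 0.0553). With blood as the reference the B6 neutrophil and B cell medians were 0.61 and 0.04 (0.725 and 0.966), and B cell markers had 0.98 with a filter of 50 (0.909). Single spleen libraries weighed on both: neutrophils had -0.76 without library 1 (0.313) and B cells -0.6 without library 2 (0.23). Cd79b, a B cell receptor component, fell from 52.4 ± 36.6 in B6 spleen to 0.724 ± 1.25 (adjusted p = 0.00658), and did not pass against blood (-1.11, 0.49). In F1, macrophage and monocyte markers had 2.43 (13 genes; 0.026) and neutrophil markers 2.82 (0.0251), each with 0.54 with an estimated correlation, and 1.81 and 1.41 without graft library 2 (0.143 each). Cxcr2, a neutrophil chemokine receptor, rose 31.2-fold in F1 to 414 ± 249 (adjusted p = 0.00149). No call was made for macrophages in B6 (1.42, 0.0808), for keratinocytes, fibroblasts, endothelium or B cells in F1 (0.89, 1.46, 1.51 and -0.14, with mean 0.32 for B cells; 0.552, 0.233, 0.217 and 0.587). Nor was one made in B6 and F1 for dendritic cells and MHC class II (9 genes; 0.31 and 1.36; 0.892 and 0.212), mast cells and basophils (5 genes; 1.35 and 2.04; 0.262 and 0.0814) or T cells (14 genes; 0.41 and 1.41; 0.788 and 0.285). The same held for ILC2 and ILC3 (5 genes; 1.20 and 1.95; 0.788 and 0.271) and erythroid cells and platelets (8 genes; -0.09 and 1.29; 0.631 and 0.564; mean 0.07 in B6).

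Most of the genes with the largest changes lay outside these lists. In B6 graft CD49b+ cells Fam124a rose by 9.37 ± 1.64, to 3114 ± 4830 (adjusted p = 0.00431), the keratin gene Krt79 by 6.76 ± 1.49 (0.0128), the collagen gene Col3a1 by 6.30 ± 1.61 (0.0274, and 0.0648 on the leukocyte scale) and the neurotrophin receptor gene Ntrk2 by 6.28 ± 1.24 (0.00705). The complement inhibitor Serping1 was listed at 0 in spleen and at 73.2 ± 32.2 in the graft (0.0287). Fgf11, an intracellular fibroblast growth factor homolog, fell by 8.10 ± 1.42 from 1144 ± 701 (0.00431), Mettl21e by 7.05 ± 1.95 (0.0397) and the calcium channel gene Cacna1c by 4.55 ± 1.27 (0.0405). Against blood, Fam124a, Fgf11, Mettl21e and Cacna1c did not pass, with changes of 4.5, 1.41, -3.92 and 0.20 (0.0983, 0.575, 0.225 and 0.941). In F1, Tctn1 rose by 10.72 ± 2.91, to 2800 ± 538 (0.0189), the potassium channel gene Kcnk3 by 8.07 ± 2.06 (0.0129), Fam81a by 6.97 ± 1.17 (0.000804) and Cd22, a B cell lectin, by 6.54 ± 1.52 (0.00727), and the cytokine gene Il1b was listed at 0 in spleen and at 153 ± 133 in the graft (0.00595). Rbpjl fell by 6.29 ± 1.60 (0.0128), D8Ertd82e by 6.26 ± 1.02 (0.000688), the regulatory T cell factor Foxp3 by 6.08 ± 1.43 (0.00763) and Ifitm10 by 5.58 ± 1.18 (0.00348). Against blood, Tctn1 and Kcnk3 did not pass, with changes of 7.5 and 5.05 (0.108 and 0.125).

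Across 16045 genes, limma counted 653 changed in B6 graft CD49b+ cells (594 higher, 59 lower) and 1956 in F1 (1698 higher, 258 lower). The models shared 405 of the higher genes against 62.9 for independent lists and 23 of the lower genes against 0.9, and their changes correlated with r = 0.63 across genes. Pan-leukocyte transcripts fell in both (-0.80 and -1.32), and their part in this was not tested. On the leukocyte scale, which moved the median of all genes from 0.33 to 1.17 in B6 and from 0.26 to 1.34 in F1, 222 genes passed in B6 (221 higher, 1 lower) and 1742 in F1 (1727 higher, 15 lower). Of these, 186 and 1474 passed on the deposited scale in the same direction, and S1pr5 in B6 no longer passed (-4.50, 0.0894). The higher and lower counts were 112 and 28 in B6 and 599 and 196 in F1 after quantile normalization, 293 and 132 in B6 with the same total outside the satellite-like genes, and 2838 and 52 in F1 with the same total. Leaving out B6 graft libraries 1, 2 or 3 gave 85, 2022 or 62 genes, and B6 spleen libraries 86, 251 or 93. Leaving out F1 graft libraries 1, 2 or 3 gave 1270, 695 or 1256, and F1 spleen libraries 845, 1050 or 862.

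**Figure D2:**
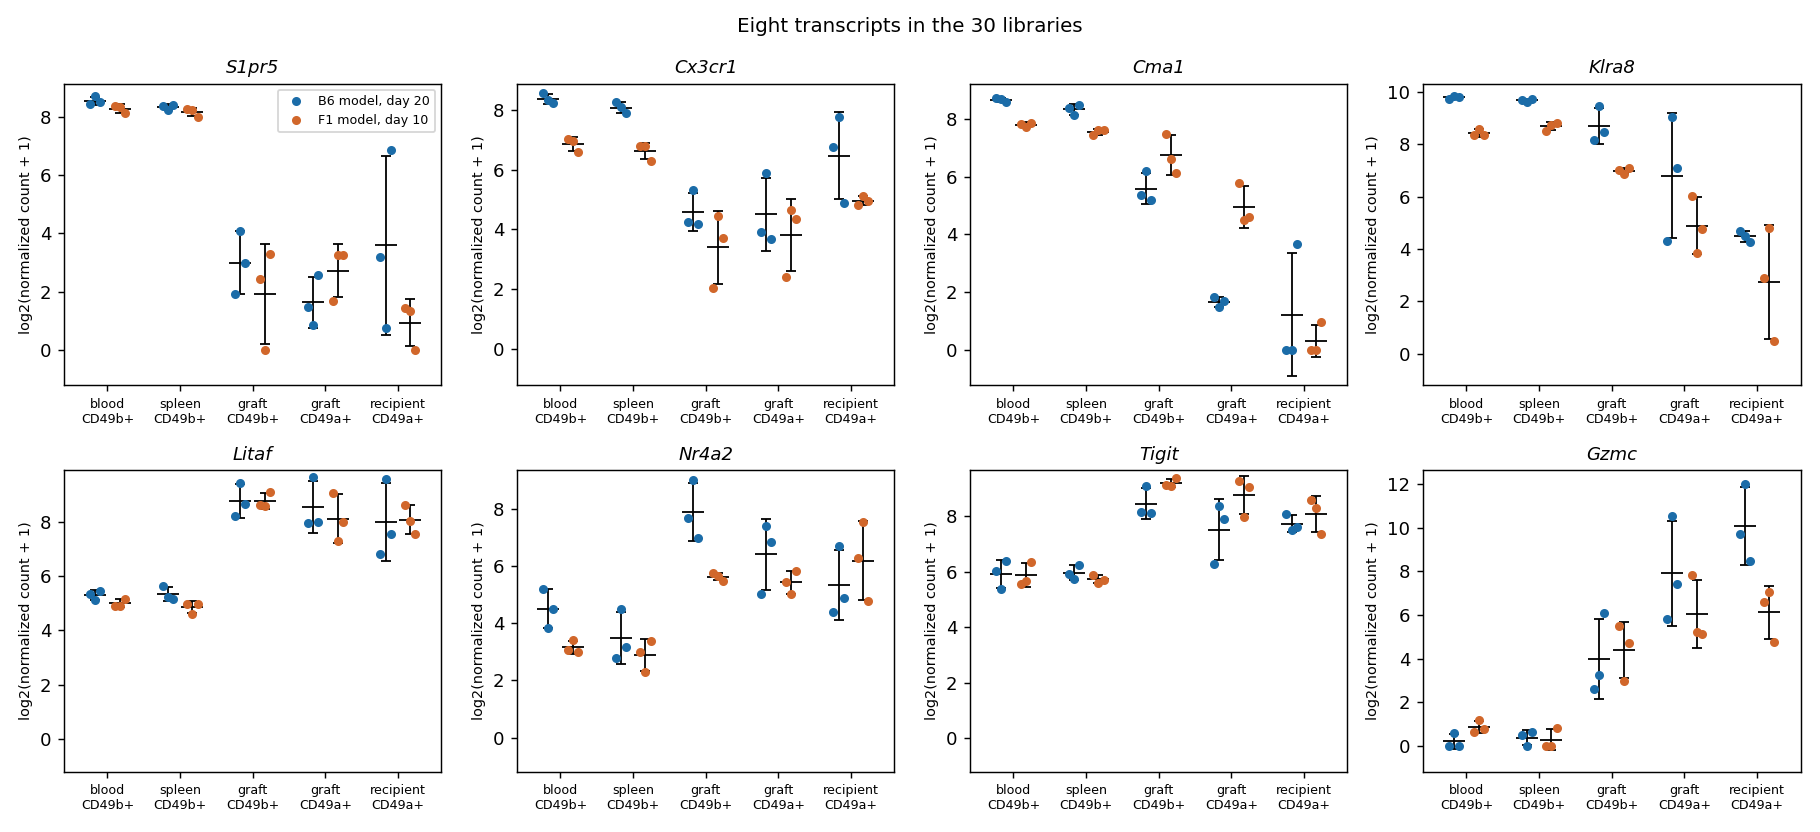
Deposited signal of 8 genes by population and model, with 1 point per library and bars at mean ± SD of log2 values. S1pr5 and Cx3cr1 fell and Litaf and Tigit rose from spleen to graft CD49b+ cells in both models.

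Within the graft, CD49a+ cells differed from CD49b+ cells in few single genes. Cma1 fell 15-fold in B6, from 49.1 ± 20.0 to 2.20 ± 0.369 (adjusted p = 0.0129), and was at 32.9 ± 18.5 against 114 ± 55.7 in F1 (adjusted p = 0.907). AA414768, a processed pseudogene, fell by 5.40 ± 0.87 in B6 (adjusted p = 0.0129). Ccdc37 rose by 5.56 ± 0.67 in F1, from 0.266 ± 0.46 to 56.5 ± 5.96 (adjusted p = 9.48e-05). None of the 3 passed on the leukocyte scale (limma adjusted p = 0.375, 0.288 and 0.0509). Itgae, which encodes the CD103 integrin, was at 260 ± 382 in CD49a+ and 16.1 ± 12.3 in CD49b+ cells of B6 grafts (adjusted p = 0.444). Klra8, which encodes the m157 receptor Ly49H and was chosen after its values were seen (chromosome 6, 130115226 to 130129898), was at 225 ± 263 and 443 ± 222 in B6 and 34.5 ± 26.2 and 127 ± 9.69 in F1, in the same order.

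Egress, maturation and receptor genes were lower as groups in CD49a+ than in CD49b+ cells of B6 grafts. In B6 the egress list had a median of -1.03 (adjusted p = 3.33e-05, and 0.00269 with an estimated correlation), with 0 of 13 genes past the threshold in limma (0 rose and 3 fell over the list alone). The egress median turned to 0.22 on the leukocyte scale (0.000385), where the median of all genes moved from 0.09 to 1.32. The NK receptor list had -1.10 (adjusted p = 3e-11; 0.22 and 0.365 without the libraries low in leukocyte transcripts) in B6 and -0.98 (3.99e-06) in F1, with adjusted p = 0.119 and 0.403 with an estimated correlation and -0.10 and -0.42 on the leukocyte scale. Klrb1c was at 63.5 ± 54.1 against 345 ± 134 in B6 (adjusted p = 0.0534), and 0 of 31 members passed in either model (limma; 5 and 1 fell over the list alone). Maturation genes had -1.02 in B6 (adjusted p = 3.33e-05, and 0.114 with an estimated correlation; 0.03 and 0.426 without the low-leukocyte libraries) and -0.45 in F1 (0.0252, and 0.439), and 0.24 and 0.09 on the leukocyte scale. Without B6 CD49a library 1 the NK receptor and maturation medians were -0.55 and -0.34 (0.000327 and 0.0149). Without F1 CD49a library 2 they were -0.6 and -0.27 (0.00485 and 0.591). In B6, ribosomal protein genes (-0.46), cytotoxic effector genes (-0.78), cytokine receptors (-0.48) and lymphocyte transcription factors (-0.64) were lower with adjusted p from 0.00098 to 0.0054, and from 0.353 to 0.905 with an estimated correlation, and all 4 medians turned positive on the leukocyte scale. Without the low-leukocyte libraries, ribosomal protein genes had -0.03, cytotoxic effector genes 0.46, cytokine receptors 0.57 and transcription factors 0.44. Each of the 4 calls was also lost without 1 library. Ribosomal protein genes had -0.07 and transcription factors -0.42 without CD49b library 2 (0.89 and 0.206). Cytotoxic effector genes had -0.4 and cytokine receptors -0.26 without CD49a library 1 (0.694 and 0.32). In F1, ribosomal protein (-0.57, adjusted p = 9.4e-06), immediate early (-0.53, 2.64e-05) and oxidative phosphorylation genes (-0.55, 0.00116) were lower, with 0.717, 0.403 and 0.732 with an estimated correlation. Without CD49a library 3 these were -0.3, -0.48 and -0.23 (0.047, 0.0577 and 0.384). The F1 maturation, ribosomal protein and immediate early medians were -0.02, 0.03 and -0.08 without the low-leukocyte libraries.

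Macrophage markers were higher in the CD49a+ graft cells of both models, with 13 of 13 genes positive in each. Their medians were 1.18 in B6 (camera adjusted p = 0.0114, and 0.696 with an estimated correlation) and 1.63 in F1 (0.000249, and 0.431). The medians were 0.57 without B6 CD49a library 1 (0.32) and 1.1 without F1 CD49a library 2 (0.0401). Without the low-leukocyte libraries the B6 macrophage median was -0.27. In F1, neutrophil markers had 2.07 (0.000718, and 0.439) and erythroid and platelet markers 3.79 (5.76e-06, and 0.403), with the globin gene Hbb-bt listed at 0 in CD49b+ and at 2758 ± 4760 in CD49a+ cells. Both rested on graft CD49a library 2, and without it their medians were 0.43 and 0.6 (0.585 and 0.532). In B6 the medians of lists without a call ran from -0.80 for cytokine and chemokine ligands (adjusted p = 0.0819) to 1.08 for erythroid markers (0.197), and the residency list had -0.16 (mean 0.11; 0.945). Without the low-leukocyte libraries, which left 1 B6 graft CD49a+ library, the B6 residency median was 1.38. In F1 the medians of lists without a call ran from -0.52 for egress genes (0.1) to 1.07 for fibroblast markers (0.0841). The F1 residency list had 0.12 (0.311).

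limma counted 2 changed genes in B6 (0 higher, 2 lower; 1041 at an unadjusted p under 0.05) and 1 in F1 (1 higher, 0 lower; 737), and a fit to the 18 skin libraries alone counted 0 in each (555 and 363 at an unadjusted p under 0.05). In simulated sets of independent genes 44.3 percent of calls were false and 12.8 percent of 4-fold changes were recovered. With the skin libraries alone these were 8.1 and 0.2 percent. On the leukocyte scale 2 genes passed in B6 (2 higher, 0 lower) and 0 in F1 (limma; 532 at an unadjusted p under 0.05). With the library number as a block, 9 genes passed in B6. Leaving out B6 graft CD49a libraries 1, 2 or 3 gave 4, 114 or 6 genes, and B6 graft CD49b libraries 2 or 3 gave 21 or 0 (limma; 907 at an unadjusted p under 0.05 for the 0). In F1 the counts were 3, 4 or 3 without CD49a libraries 1, 2 or 3 and 2, 6 or 4 without CD49b libraries 1, 2 or 3.

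Compared with CD49a+ cells of the recipient's own skin, CD49a+ cells of the B6 graft had more interferon-induced transcripts. Cxcl10, an interferon-induced chemokine, rose 27.0-fold, from 3.16 ± 3.68 to 104 ± 94.1 (adjusted p = 0.0376). The guanylate-binding protein gene Gbp3 rose 20.4-fold, from 1.64 ± 1.49 to 60.1 ± 46.3 (adjusted p = 0.00955). Of 28 type I interferon response genes, 2 rose and 0 fell (13 and 1 over the list alone), 23 were positive and the median was 1.5 (adjusted p = 4.28e-08, and 0.37 with an estimated correlation). Gbp3 passed on the leukocyte scale (adjusted p = 0.0122), while Cxcl10 did not (0.0602), nor did it with the replicate block (0.0555). Without single libraries, Cxcl10 lost its call in 4 of 6 fits and Gbp3 in 1. In F1 the interferon list had a median of 0.33 (adjusted p = 0.536), and of -0.52 without recipient library 3 (0.0228) and -0.93 without the low-leukocyte libraries (0.0427).

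Other genes of the B6 graft CD49a+ cells also exceeded recipient skin. Oacyl rose by 6.84 ± 1.43, to 332 ± 268 (adjusted p = 0.0376), the replication factor gene Atad5 58.6-fold (0.0116), the ATP synthase gene Atp5g2 25.5-fold (0.0375) and the growth regulator Myc 7.61-fold (0.0372, and 0.168 on the leukocyte scale). The DNA repair nuclease gene Dclre1b fell 15.3-fold (0.0204) and Rabggta, a prenyltransferase subunit gene, 4.82-fold (0.0429, and 0.221 on the leukocyte scale). With the replicate block Oacyl, Myc and Rabggta did not pass (0.0586, 0.0526 and 0.07). Of 6 fits without 1 library, Oacyl, Atp5g2, Myc and Rabggta lost their call in 4, Dclre1b in 3 and Atad5 in 1. Ribosomal protein genes were positive in 24 of 24 (median 1.38, adjusted p = 4.51e-12, and 0.629 with an estimated correlation), oxidative phosphorylation genes in 20 of 22 (0.95, 0.000185, and 0.753) and cell cycle genes in 24 of 33 (0.77, 0.00494, and 0.629). NK receptors had 0.52 (23 of 31 positive, 0.0425, and 0.803 with an estimated correlation), and -0.09 without B6 graft CD49a library 2 (0.425). Macrophage markers moved with them, with a median of 2.04 (0.00553, and 0.753 with an estimated correlation; 0.97 and 0.154 without graft library 1).

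In F1, cell cycle genes set graft CD49a+ cells apart from recipient skin. Mcm5, a subunit of the replicative helicase, rose 9.86-fold, from 11.7 ± 13.2 to 82.4 ± 17.1 (adjusted p = 0.0215; 0.413 on the leukocyte scale and 0.0541 with the replicate block). Of 33 cell cycle genes, 1 rose and 0 fell (8 and 0 over the list alone), 32 were positive, and the median was 1.62 (adjusted p = 4.53e-11, and 0.02 with an estimated correlation; 1.06 and 3.68e-05 without graft library 2). The median on the leukocyte scale was 1.10 and that p was 0.145. Cma1 rose 24.8-fold, from 0.316 ± 0.548 to 32.9 ± 18.5 (adjusted p = 0.000685, and 0.0775 on the leukocyte scale), and Ccdc37 33.2-fold (0.000591, and 0.126 on the leukocyte scale). Immediate early genes were lower, with 2 of 23 positive and a median of -1.06 (adjusted p = 4.93e-14, and 0.0222 with an estimated correlation; 0 of 23 past the threshold in limma, and 7 fell over the list alone). The immediate early median on the leukocyte scale was -1.68, and its p was 0.0929 with an estimated correlation. Their member Dusp1 was at 79.7 ± 42.1 against 458 ± 188 (adjusted p = 0.0587).

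Further groups separated the F1 graft and recipient skin CD49a+ cells. NK receptors had a median of 0.67 (27 of 31 positive, adjusted p = 0.00107; 0.31 and 0.208 without graft library 1), maturation genes 0.75 (12 of 14, 0.00657), cytotoxic effector genes 0.90 (0.00199) and oxidative phosphorylation genes -0.62 (5.74e-05; 0.08 and 0.728 without recipient library 3, and 0.51 and 0.312 without the low-leukocyte libraries). Markers of macrophages (2.01, 0.000261; -1.10 and 0.434 without the low-leukocyte libraries), neutrophils (2.56, 7.77e-05; 0.73 and 0.808), mast cells (1.48, 0.0228) and erythroid cells (4.86, 4.86e-08; 2.02 and 0.0238 without graft library 2) were higher and those of keratinocytes (-1.46, 0.00399) lower. With an estimated correlation their adjusted p was 0.323 for maturation, macrophages, neutrophils and mast cells, 0.0903 for erythroid cells and 0.388 for the others. Without recipient library 3, maturation genes had 0.18 (0.265), cytotoxic genes 0.26 (0.114), macrophages 0.49 (0.168), mast cells 0.61 (0.347) and keratinocytes -0.74 (0.15). In B6 the medians of lists without a call ran from -0.68 for mast cells (0.366) to 1.92 for keratinocytes (0.0662). In F1 they went from -0.43 for lipid handling (0.237) to 1.07 for B cells (0.0549).

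limma counted 36 changed genes in B6 (31 higher, 5 lower; 1961 at an unadjusted p under 0.05) and 4 in F1 (3 higher, 1 lower; 1304), 0 of them shared (limma; r = -0.07 across genes), and 0 in each with the 18 skin libraries alone (1047 and 661 at an unadjusted p under 0.05). The remaining F1 gene, Pop1, fell by 4.18 ± 0.71 (adjusted p = 0.0164, and 0.0775 on the leukocyte scale) and was chosen after its values were seen. In simulated sets 42.4 percent of calls were false and 15.1 percent of 4-fold changes were recovered. With the skin libraries alone these were 20.0 and 0.5 percent. With the library number as a replicate block, paired by number, 21 genes passed in B6 (19 higher, 2 lower), and with the same total 15 were higher and 8 lower, or 6 and 0 outside the satellite-like genes. On the leukocyte scale 88 passed in B6 (82 higher, 6 lower) and 0 in F1 (limma; 1223 at an unadjusted p under 0.05), with the median of all genes at 0.17 and -0.36 in F1 before and after. Leaving out B6 graft libraries 1, 2 or 3 gave 17, 142 or 12 genes, and recipient libraries 1 or 2 gave 19 or 1013. In F1 the counts were 9, 8 or 18 without graft libraries 1, 2 or 3 and 46, 12 or 61 without recipient libraries 1, 2 or 3.

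In this fit, spleen and blood CD49b+ cells were told apart mainly by gene groups. In F1, cell cycle genes were higher in spleen, with 31 of 33 positive and a median of 1.92 (adjusted p = 1.4e-32, and 2.47e-05 with an estimated correlation; 0 of 33 past the threshold in limma, and 13 rose and 1 fell over the list alone). Birc5, a mitotic survivin gene, was at 101 ± 37.1 in spleen and 13.9 ± 3.10 in blood (adjusted p = 0.389), and Rrm2, a ribonucleotide reductase subunit gene, at 106 ± 38.2 and 10.3 ± 2.07 (0.433). In B6 the cell cycle median was 0.18 (adjusted p = 0.465). B6 spleen instead had higher markers of B cells (median 2.92, adjusted p = 2.3e-29), dendritic cells and MHC class II (2.41, 2.99e-15), neutrophils (3.09, 1.57e-17) and T cells (0.64, 0.00067), with adjusted p = 4.73e-06, 0.000334, 0.00776 and 0.00819 with an estimated correlation. Macrophage markers had 0.70 (0.000977, and 0.41 with an estimated correlation), TGF-beta response genes -0.26 (0.0493, and 0.0734) and erythroid markers -3.26 (5.4e-11, and 0.0177). In F1, erythroid markers had -2.66 (1.77e-05, and 0.392) and ribosomal protein genes 0.28 (0.00139, and 1.0). In B6, B cell markers had 1.4 without spleen library 2 (0.000116) and neutrophil markers 1.45 without spleen library 1 (9.99e-05). The TGF-beta call was lost without blood library 1 (-0.23, 0.179).

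Single genes rarely separated spleen from blood. Fgf11 rose 725-fold in B6 spleen, from 0.494 ± 0.636 to 1144 ± 701 (adjusted p = 0.00531), and the predicted gene Gm10083, chosen after its values were seen, rose by 9.44 ± 1.49 in F1 (adjusted p = 0.0135, and 0.211 on the leukocyte scale). limma counted 1 gene in each model (229 and 474 at an unadjusted p under 0.05), and on the leukocyte scale 1 and 0 (216 at an unadjusted p under 0.05 for the 0). Leaving out B6 blood libraries 1, 2 or 3 gave 2, 0 or 2 genes (limma; 205 at an unadjusted p under 0.05 for the 0) and spleen libraries 5, 4 or 2; in F1 the counts were 9, 6 or 5 and 6, 7 or 2.

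Recipient skin CD49a+ cells differed from spleen CD49b+ cells in granzymes and chemokines. Gzmc rose 834-fold in B6, from 0.317 ± 0.281 to 1793 ± 2080 (adjusted p = 9.25e-07), and 57.8-fold in F1, to 84.2 ± 54.1 (0.000847). Gzma, the granzyme of circulating NK cells, fell 221-fold in B6, from 5331 ± 258 to 225 ± 372 (0.000288), and 25.5-fold in F1 (0.0142, and 0.128 on the leukocyte scale). Perforin, encoded by Prf1, fell 26.9-fold in B6 to 130 ± 180 (0.000542) and 10.1-fold in F1 to 140 ± 47.6 (0.0105, and 0.145 on the leukocyte scale). Ccl5 fell 143-fold and 45.3-fold (1.39e-06 and 9.67e-05). Itgae rose 85.0-fold in B6, from 4.84 ± 1.53 to 746 ± 811 (0.000179), and was at 63.4 ± 50.5 against 6.28 ± 0.214 in F1 (0.0542). The chemokine receptor gene Ccr8 rose 67.9-fold in B6 to 155 ± 191 (0.000184), and the growth factor gene Areg was listed at 0 in B6 spleen and at 142 ± 183 in recipient skin (0.000388).

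Residency genes were higher and egress genes lower in recipient skin in both models. Of 23 residency genes, 15 rose and 0 fell in B6 (17 and 0 over the list alone; median 2.51, adjusted p = 3.59e-05), and 11 rose and 1 fell in F1 (13 and 1; 2.41, 0.000725). Their adjusted p was 0.271 and 0.517 with an estimated correlation, and 0.000661 and 0.00202 on the leukocyte scale. Nr4a1 rose 19.7-fold and 8.34-fold (0.000288 and 0.0053), and Litaf 6.19-fold and 9.22-fold (0.00184 and 0.000837). Of 13 egress genes, 9 fell in B6 and 6 in F1, and 0 rose in either (limma; 11 and 10 fell over the list alone; medians -2.67 and -2.65; adjusted p = 3.7e-07 and 3.64e-07, and 0.000349 and 0.000347 with an estimated correlation; -1.44 and -0.33 on the leukocyte scale). S1pr5 fell 26.8-fold in B6 (0.00119, and 0.14 on the leukocyte scale) and by 7.23 ± 0.95 in F1, from 287 ± 26.7 to 1.09 ± 0.949 (3.81e-05).

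NK receptor and maturation genes were also lower in recipient skin. Klra4, which encodes Ly49D, fell 108-fold in B6, from 857 ± 40.2 to 9.15 ± 6.59 (2.26e-07), and 35.9-fold in F1 (2.12e-05). Klrb1c fell 50.9-fold and 14.3-fold (2.26e-07 and 8.61e-05). Of 31 NK receptor genes, 20 fell in B6 and 21 in F1 and 0 rose (limma; 20 and 24 fell and 1 and 0 rose over the list alone), with medians of -2.63 and -3.23 (adjusted p = 9.98e-13 and 4.33e-20; 0.108 and 0.0143 with an estimated correlation; -0.43 and -1.03 on the leukocyte scale). Cma1 fell by 7.09 ± 0.64 in B6 and 7.23 ± 0.64 in F1 (1.11e-07 and 8.79e-08), and Klrg1 119-fold and 13.9-fold (4.67e-07 and 0.00128; 0.126 in F1 on the leukocyte scale). Of 14 maturation genes, 6 fell in each model and 1 rose in B6 (8 and 6 fell over the list alone; medians -2.0 and -1.85; 5.22e-05 and 7.02e-06; 0.108 and 0.0454 with an estimated correlation). The medians turned to 0.34 and 0.32 on the leukocyte scale, where camera still called them lower (adjusted p = 0.000402 and 0.000995).

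Immediate early genes were higher and cell cycle and ribosomal protein genes lower in recipient skin. The immediate early gene Fos rose 19.4-fold in B6 and 21-fold in F1 (8.13e-05 and 6.67e-05), and 10 of 23 list members rose in each and 1 fell in B6 (12 and 11 rose over the list alone; medians 1.43 and 1.80; adjusted p = 0.0129 and 3.1e-05; 0.528 and 0.246 with an estimated correlation). In F1, 17 of 33 cell cycle genes fell and 0 rose (limma; 20 over the list alone; median -2.51, 1.06e-12, and 0.00502 with an estimated correlation; -0.45 on the leukocyte scale), and Mcm5 fell 14.4-fold (0.000227, and 0.146 on the leukocyte scale). In B6, 10 fell and 1 rose (10 and 2 over the list alone; -0.25, 0.0347, and 0.505), a median that turned positive on the leukocyte scale and with the same total. Ribosomal protein genes fell in 20 of 24 in B6 and 3 of 24 in F1 (23 and 3 over the list alone; medians -2.01 and -0.96; 9.98e-13 and 2.84e-06; 0.255 and 0.524 with an estimated correlation), with medians of 0.24 and 1.37 on the leukocyte scale. TGF-beta response genes had 1.68 and 2.28 (0.0364 and 0.0246; 0.133 and 0.0671), and Furin, a protease that processes the TGF-beta precursor, rose 11.4-fold and 5.01-fold (0.000358 and 0.0105). Cytotoxic effector genes had -0.60 and -1.10 (0.00636 and 0.0142; 0.505 and 0.524), both turning positive on the leukocyte scale and with the same total. Without recipient library 3 these were -0.21 and -0.7 (0.0361 and 0.13). Without recipient library 2 the B6 immediate early and cell cycle medians were 1.11 and -0.86 (0.29 and 0.102). The TGF-beta medians were then 1.96 and 2.04 (0.124 and 0.0894).

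In B6 recipient skin, oxidative phosphorylation (median -1.27, adjusted p = 8.85e-05), type I interferon response (-0.61, 0.0347) and cytokine receptor genes (-0.45, 0.045) were lower, with 0.505, 0.553 and 0.61 with an estimated correlation, and all 3 medians turned positive on the leukocyte scale; the cytokine receptor median was 0.51 without the low-leukocyte libraries (0.294). Without 1 recipient library the cytokine receptor and interferon calls were lost, at -0.14 without library 3 and -0.64 without library 2 (0.221 and 0.106). Among markers of other cells, B cells had -2.37 in B6 (0.00207, and 0.167; 0.83 and 0.884 with a filter of 50; -0.19 and 0.321 without spleen library 2) and keratinocytes 3.12 in F1 (0.0142, and 0.524; 2.94 and 0.119 without recipient library 3). The other marker lists had no call: their medians ran from -1.55 for neutrophils (0.252) to 3.16 for keratinocytes (0.0579) in B6 and from -0.52 for B cells (0.243) to 2.98 for fibroblasts (0.0555) in F1. Inhibitory receptors had 0.66 and 1.06 (0.35 and 0.179), although Tigit rose 3.40-fold and 5.12-fold (0.00936 and 0.00244).

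The largest changes in recipient skin included further single genes. In B6 the homeobox gene Mkx rose by 8.31 ± 1.39 (0.000314), Igfbp3, which binds insulin-like growth factors, by 6.62 ± 1.15 (0.000382), AW112010 fell 258-fold from 2809 ± 102 (0.00015), and the pattern receptor gene Nod1 was listed at 0 in recipient skin and at 196 ± 21.5 in spleen (1.3e-12). In F1 the interferon-induced Ifitm2 and Ifitm3 rose 122-fold and 120-fold (2.74e-06 and 3.02e-05), the stress factor gene Atf3 rose to 173 ± 126 (0.000159), and the cyclin gene Ccnb2 was listed at 0 in recipient skin and at 65.7 ± 23.3 in spleen (0.000487). limma counted 4625 changed genes in B6 (2866 higher, 1759 lower) and 2524 in F1 (1812 higher, 712 lower); the models shared 1279 higher genes against 323.7 for independent lists and 397 lower genes against 78.1 (r = 0.7 across genes). On the leukocyte scale, which moved the median of all genes from 0.40 to 2.46 in B6 and from 0.36 to 2.43 in F1, 6990 were higher and 169 lower in B6 and 6865 and 73 in F1. The higher and lower counts were 4708 and 509 in B6 and 4893 and 194 in F1 with the same total, 1432 and 1764 and 734 and 601 after quantile normalization, and 2196 and 2976 in B6 with the same total outside the satellite-like genes. Population, tissue and leukocyte level differ together in this comparison. Leaving out B6 recipient libraries 1 or 3 gave 2529 or 2571 genes, and spleen libraries 1 or 3 gave 2776 or 2816. In F1 the counts were 1341, 1146 or 4499 without recipient libraries 1, 2 or 3 and 1376, 1500 or 1361 without spleen libraries.

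**Figure D3:**
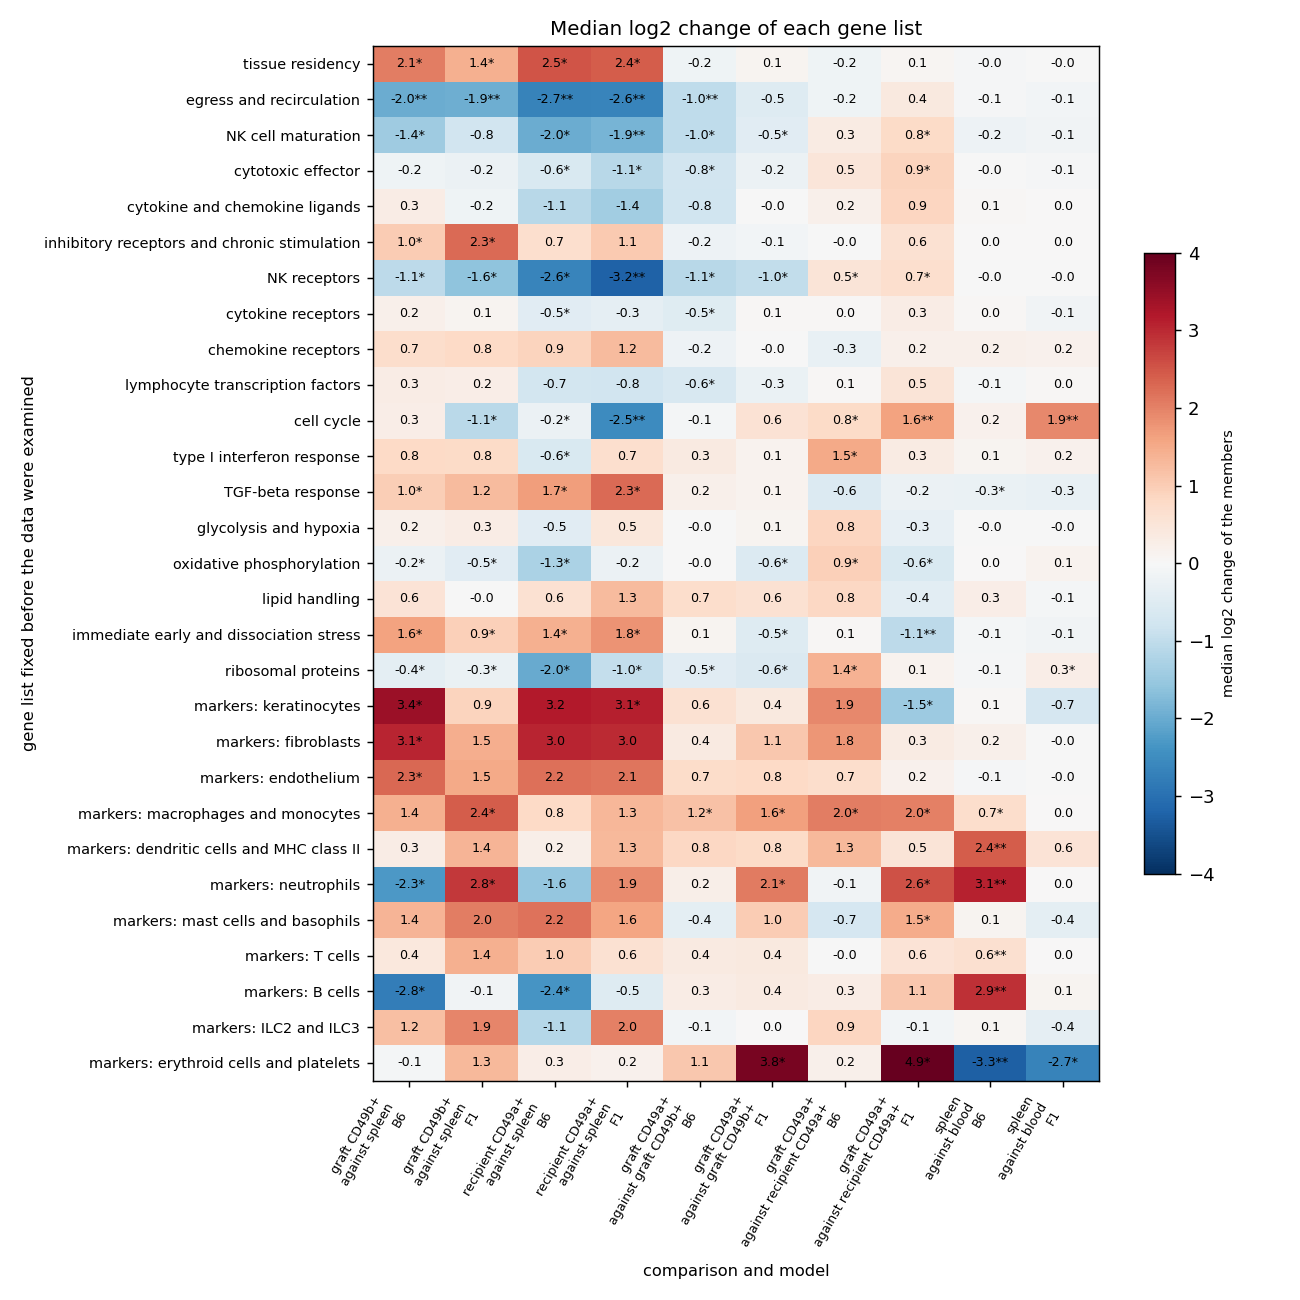
Median log2 change of 29 gene lists in 10 comparisons on the deposited scale. A star marks a camera adjusted p under 0.05 with a preset correlation of 0.01, and 2 stars mark lists that also passed with an estimated correlation; medians of ribosomal protein, oxidative phosphorylation and maturation lists, among others, change sign on the leukocyte scale.

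The change from spleen to graft CD49b+ cells differed between the models in cell cycle genes, a difference that depended on the spleen reference. The F1 change minus the B6 change had a median of -1.56 (adjusted p = 5.84e-08, and 0.0301 with an estimated correlation), and of 0.22 with blood as the reference (0.448). Markers of neutrophils (4.14) and B cells (2.88) differed the other way (1.56e-12 and 1.68e-06; 0.0301 each with an estimated correlation), by 1.57 and -0.26 with blood (0.0407 and 0.489). No single gene differed in limma (0 genes; 512 at an unadjusted p under 0.05), and leaving out B6 spleen library 1, F1 graft library 2 or F1 spleen library 2 gave 2, 3 or 2. For graft CD49a+ against CD49b+ cells, 38 of 100 splits gave 1 gene or more. Ccdc37 differed there by 5.60 ± 0.94 (adjusted p = 0.0397, 561 genes at an unadjusted p under 0.05). It did not pass on the leukocyte scale (1.0), and 0 genes passed with the replicate block (limma; 600 at an unadjusted p under 0.05).

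Between the models 3 genes differed for graft against recipient CD49a+ cells, but 72 of 100 splits gave as many or more. The kinase gene Abl2 differed by -6.95 ± 1.20, and mt-Nd3, a mitochondrial complex I gene, and Ascc1, both chosen after their values were seen, by -4.17 ± 0.71 and -5.09 ± 0.89 (adjusted p = 0.0209 each). On the leukocyte scale Abl2 and Ascc1 passed (0.0387 and 0.00942) and mt-Nd3 did not (0.139), and with the replicate block Abl2 and mt-Nd3 passed (0.0217 each) and Ascc1 did not (0.0653). The interferon list differed by -1.38 (adjusted p = 0.000779, and 0.464 with an estimated correlation; -1.03 and 0.0749 without F1 recipient library 1). Mitochondrial genes held 5.77 ± 3.58 percent of the signal outside the satellite-like genes in B6 graft CD49a+ cells and 1.99 ± 1.17 in recipient skin. In F1 they held 0.91 ± 0.42 and 4.44 ± 2.62 percent. The part of RNA quality in these differences was not tested. limma counted 3 genes there (1786 at an unadjusted p under 0.05), 32 on the leukocyte scale, and 0 for both graft CD49a+ differences with the skin libraries alone (295 and 900 at an unadjusted p under 0.05). For graft CD49a+ against CD49b+ cells, the count of 1 became 8 without B6 CD49a library 2, 4 and 2 without B6 and F1 CD49b library 2, and 0 without B6 CD49a library 3, B6 CD49b libraries 1 or 3, any F1 CD49a library or F1 CD49b libraries 1 or 3 (limma; 519 to 675 at an unadjusted p under 0.05). For graft against recipient CD49a+ cells, the count of 3 became 7, 72 or 0 without B6 graft libraries 1, 2 or 3 (limma; 1878 at an unadjusted p under 0.05 for the 0), 29, 473 or 28 without B6 recipient libraries, 8 or 11 without F1 graft libraries 1 or 2, and 56, 12 or 15 without F1 recipient libraries. Genotype, strain, graft B2m and day differ together between the models, and the p-values measure spread between libraries, which the labels do not say came from separate animals.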

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

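Tests without the libraries low in leukocyte transcripts were chosen only after the result was seen; those that swapped the reference tissue for the neutrophil and B cell markers were planned as an alternative, but their use to weigh an explanation was chosen after it too. The differences below came from planned tests of the F1 change minus the B6 change.

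Chance was not excluded for 4 single genes whose difference between the models passed. Ccdc37 differed by 5.60 (adjusted p = 0.0397) in graft CD49a+ against CD49b+ cells. It did not pass on the leukocyte scale (1.0) or with the replicate block (0.129). In graft against recipient CD49a+ cells mt-Nd3 differed by -4.17, Ascc1 by -5.09 and Abl2 by -6.95 (adjusted p = 0.0209 each). On the leukocyte scale mt-Nd3 did not pass (0.139), and with the replicate block Ascc1 did not (0.0653).

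Gene lists differed between the models in graft CD49b+ cells against spleen. The medians were -0.49 for tissue residency (adjusted p = 0.0422), -0.57 for NK receptors (0.0363), -0.35 for immediate early genes (0.0433), -2.51 for keratinocyte markers (0.00186) and -1.65 for fibroblast markers (0.0327), with adjusted p from 0.729 to 0.761 with an estimated correlation. Without B6 graft library 2 the first 3 were -0.54, -0.33 and -0.22 (0.278, 0.412 and 0.285), and without B6 graft library 1 fibroblast markers had -0.91 (0.522). Cell cycle genes differed by -1.56 (5.84e-08, and 0.0301 with an estimated correlation), and by 0.22 with blood as the reference (0.448). In graft CD49a+ against CD49b+ cells, cytokine receptors differed by 0.60 and immediate early genes by -0.59 (0.0403 each, and 0.913 each with an estimated correlation). Without the low-leukocyte libraries these were -0.19 and 0.11, and without B6 CD49a library 1 alone 0.21 and -0.24 (camera adjusted p = 0.658 and 0.354). In graft against recipient CD49a+ cells, the differences were -1.38 for type I interferon response (0.000779), -1.05 for glycolysis and hypoxia (0.0266), -1.54 for oxidative phosphorylation (1.38e-07), -1.38 for lipid handling (0.0376), -1.39 for immediate early genes (8.77e-07), -1.23 for ribosomal proteins (2.62e-06) and -3.41 for keratinocyte markers (0.00103). There, markers of neutrophils differed by 2.75 (0.00293), mast cells by 2.73 (0.0293) and erythroid cells by 4.03 (0.003), and all of these lists had 0.464 or 0.467 with an estimated correlation. Without F1 graft CD49a library 2 the erythroid and neutrophil differences were 1.74 and 2.14 (0.211 and 0.139). Without F1 recipient library 3, glycolysis had -0.56, lipid handling -1.12 and mast cells 1.68 (0.428, 0.475 and 0.208). Interferon response had -1.03 without F1 recipient library 1 (0.0749) and keratinocytes -2.24 without B6 graft library 1 (0.0665). The mitochondrial share also ran opposite ways there, at 5.77 percent in graft and 1.99 in recipient skin in B6, and at 0.91 and 4.44 in F1. Its part in these lists was not tested. Without the low-leukocyte libraries 7 of them turned, to 0.28 for glycolysis, 0.14 for oxidative phosphorylation, 1.53 for lipid handling, 0.38 for immediate early genes, 0.61 for ribosomal proteins, 1.18 for keratinocytes and -0.86 for neutrophils (adjusted p from 0.15 to 0.964).

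Neutrophil and B cell markers differed between the models in graft CD49b+ cells against spleen, by 4.14 and 2.88 (adjusted p = 1.56e-12 and 1.68e-06, and 0.0301 each with an estimated correlation). With blood in place of spleen the B cell difference was -0.26 (adjusted p = 0.489), and with spleen but without B6 spleen library 2 it was 1.34 (0.258), so B cell RNA in the B6 spleen libraries, where Cd79a was at 54.8 ± 45.1 against 2.09 in F1, is a candidate source; 3 of the 10 B cell markers reached 10 in blood NK cells and 0 stand in another list. The neutrophil difference with blood was 1.57 (adjusted p = 0.0407), which leaves neutrophil RNA in the B6 spleen libraries, with S100a9 at 92.1 ± 80.0, open for part of it; 1 of its 10 markers reached 10 in blood. The NKp46-GFP sort should exclude both cell types. Genotype, strain, graft B2m and day stay open as untested biological differences.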

How the results depend on the processing

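Tests chosen only after the results were seen were those on the leukocyte scale, with the same total without satellite-like genes, with the skin libraries alone and without the libraries low in leukocyte transcripts; the others were planned. Planned edgeR and DESeq2 tests on recovered reads were not run, because whole reads were not recovered. Where a value moved or turned, the cause was not tested, except that fewer genes or libraries enter by construction with another filter, a fit of fewer libraries or a left-out library. Gene counts not given below lay within 1.5 times. Small changes were rarely found, and the part of depth in this was not tested: at most 1.7 percent of simulated 2-fold changes were recovered.

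Of 110 called list results, 95 kept direction and call with array weights, 107 without a filter, 101 with a pseudocount of 10, 100 after quantile normalization, 109 with the replicate block, 96 with the same total, 98 with the same total without satellite-like genes and 87 on the leukocyte scale. With an estimated correlation 19 of 110 kept their call and 0 turned (camera). With a filter of 50, 78 of 108 were kept, with each model alone 83 of 90, with skin alone 42 of 45, with blood as the reference 38 of 55, without the low libraries 68 of 110 and over single left-out libraries 643 of 780, with 55 of the 110 kept whichever library was left out. Of 230 called named genes, 217 were kept with array weights, 208 without a filter, 181 with a pseudocount of 10, 172 after quantile normalization, 223 with the block, 196 with the same total, 205 with the same total without satellite-like genes and 158 on the leukocyte scale. With skin alone 0 of 16 were kept in limma, with each model alone 186 of 228, with a filter of 50 184 of 188, without the low libraries 186 of 215, with blood 174 of 213 and over left-out libraries 1014 of 1375, with 129 of the 230 kept throughout.

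Counts are given for graft CD49b+ against spleen (A), graft CD49a+ against CD49b+ (C), graft against recipient CD49a+ (D), spleen against blood (E) and recipient skin against spleen (F), B6 before F1, and for the differences between the models (dA, dC, dD). A pseudocount of 10 gave A 272 and 905, C 18 and 2, D 11 and 28, E 5 and 2, and F1 F 1616. No filter gave B6 A 394, C 7 and 19, D 64 and 43, E 4 and 4, dA 1, dC 4 and dD 20. A filter of 50 gave F1 A 1053, C 13 and 0 (limma; 295 at an unadjusted p under 0.05), F 2554 and 1516, and dC 0 (242). Quantile normalization gave A 140 and 795, D 19 and 28, F1 F 1335, dA 1 and dD 6. The same total gave B6 C 0 (limma; 880 at an unadjusted p under 0.05), D 23 and 22, F1 F 5087 and dD 21. Array weights gave A 4002 and 5101, C 27 and 2, E 53 and 83, F1 F 4679, dA 19 and dD 6. The replicate block gave B6 C 9, B6 D 21, F1 E 3 and dC 0 (limma; 600). Each model alone gave B6 A 78, B6 C 0 (limma; 855), B6 D 7, and E 8 and 5. Blood as the reference gave F1 A 1221.

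The leukocyte scale gave B6 A 222, F1 C 0 (limma; 532 at an unadjusted p under 0.05), D 88 and 0 (1223), F1 E 0 (216), F 7159 and 6938, and dD 32. The same total without satellite-like genes gave B6 A 425, D 6 and 17, E 3 and 4, dA 3 and dD 12. Skin alone gave 0 for C (limma; 555 and 363 at an unadjusted p under 0.05), D (1047 and 661), dC (295) and dD (900). Without the low libraries the counts were A 2932 and 4168, C 106 and 37, D 227 and 1037, F1 E 7, F 1452 and 4996, dA 26, dC 42 and dD 525. Over single left-out libraries the ranges were A 62 to 2022 and 695 to 1270, C 0 to 114 and 2 to 6, D 12 to 1013 and 8 to 61, E 0 to 5 and 2 to 9, F 2529 to 6855 and 1146 to 4499, dA 0 to 3, dC 0 to 8 and dD 0 to 473 (limma; 205 to 1878 at an unadjusted p under 0.05 beside the counts of 0). The 8 low libraries were B6 graft CD49a 1 and 3, B6 recipient 1 and 3, F1 graft CD49a 2 and 3, and F1 recipient 2 and 3, at 9.09, 15.3, 11.6, 9.44, 24.8, 20.1, 17.5 and 11.1 percent of the circulating level.

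Directions turned in the following results, where the direction of a list is that of camera against all other genes and the value is the median. The medians of further called lists crossed 0 while camera kept its direction: 20 on the leukocyte scale, 10 with the same total, 2 with blood as the reference, 1 with a pseudocount of 10 and 1 without the low libraries. With a filter of 50, B cell markers had 0.98 in A and 0.83 in F of B6. With the same total, ribosomal proteins had 0.70 in A and Uqcrfs1 1.35 in F of F1. With blood as the reference, B6 A had neutrophils 0.61, B cells 0.04, Fgf11 1.41 and Cacna1c 0.20, F1 A cell cycle 0.61, B6 F Hba-a2 -6.46, and dA cell cycle 0.22, ribosomal proteins 0.40 and B cells -0.26. Ribosomal proteins had, on the leukocyte scale, 0.96 in F1 A and 0.83 in B6 C. There B6 F had cytokine receptors 1.92, Cd244 1.31, Tbx21 0.05, Mcm5 0.06, Uqcrfs1 0.19, Sdhb 0.74 and Rps14 0.16, and F1 F had Uqcrfs1 2.35, Rplp1 0.61 and Rps14 0.93. Without single libraries, NK receptors in B6 D ran from -0.09 (without graft CD49a library 2) to 1.41, ribosomal proteins in dA from -0.27 to 0.43 (without B6 graft CD49b library 2), and in F1 D the interferon list from -0.52 to 0.86 and oxidative phosphorylation from -1.11 to 0.08, with -0.52 and 0.08 without recipient library 3.

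Without the low libraries, B6 C turned for residency 1.38, cytotoxic genes 0.46, inhibitory receptors 1.13, NK receptors 0.22, cytokine receptors 0.57, transcription factors 0.44, ribosomal proteins -0.03, keratinocytes -3.15, fibroblasts -3.88 and macrophages -0.27. F1 C turned for maturation -0.02, ligands 0.90, inhibitory receptors 0.54, immediate early genes -0.08 and ribosomal proteins 0.03. D turned for immediate early genes -0.93 in B6 and, in F1, for interferon response -0.93, oxidative phosphorylation 0.51, macrophages -1.10, dendritic cells -2.02, neutrophils 0.73 and Hmgcs1 1.78. B6 F turned for cytokine receptors 0.51 and Tbx21 0.10. The differences turned in dC for cytokine receptors -0.19, immediate early genes 0.11 and keratinocytes 3.16, and in dD for glycolysis 0.28, oxidative phosphorylation 0.14, lipid handling 1.53, immediate early genes 0.38, ribosomal proteins 0.61, keratinocytes 1.18 and neutrophils -0.86. In groups left with 1 library, that library is assumed to vary like the others.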

Other observations

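Tests of the receptor family, of relative list scores and of residency genes outside the immediate early set were chosen only after the results were seen. The other splits of the libraries, run for every count, were also made after. Only the count of libraries low in Lyz2 was set before.

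Circulating NK cells of the models differed in their receptor transcripts. In blood and spleen together, Klra8 was lower in F1 by a mean log2 difference of -1.17, at 344 ± 35.9 against 882 ± 34.6 in blood and 413 ± 46.0 against 815 ± 28.6 in spleen. The related Klra1 (-1.19), Klra4 (-0.91), Klra7 (-0.70) and Klra9 (-0.64), and Klrb1c (-0.55) and Klrc2 (-0.57), were also lower. Ncr1 was higher by 1.32, at 946 ± 69.2 against 364 ± 42.0 in blood, as were Klri1 by 2.21, Klra3 by 0.86, Klrb1f by 0.46 and Klrb1a by 0.31. In an exact permutation of the 12 libraries within each tissue, each of these 12 genes had p = 0.005, the smallest that 400 arrangements can give. The adjusted p was 0.0107 (Benjamini-Hochberg over a family of 32), and the models did not overlap in either tissue. Blood and spleen libraries counted as separate units here, and the labels do not say whether they share animals. If they do, fewer arrangements exist and the smallest possible p is larger. In that family 9 genes were higher and 13 lower in F1. The family was chosen after the values of Ncr1 and Klra8 were seen, and differences between strain alleles and related genes were not separated. Ncr1 carries iCre on both alleles in B6 and on 1 in F1 recipients, which was not separated from strain.

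NK receptor, egress and ribosomal protein transcripts were lower in the 12 CD49a+ skin libraries than in the 12 circulating ones, by -2.37, -2.59 and -1.17 (log2), while pan-leukocyte transcripts differed by -2.11. The ribosomal score relative to pan-leukocyte transcripts was 0.94 higher in skin (permutation p = 0.001, adjusted p = 0.003 over 3 lists). Less leukocyte mRNA alone would not raise this score and stays undecided. For NK receptors (-0.27, permutation p = 0.11, adjusted p = 0.11) and egress genes (-0.49, permutation p = 0.059, adjusted p = 0.088) less leukocyte mRNA and lower transcript levels per cell cannot be told apart, although among the 4 CD49a+ skin libraries less than 2 log2 units below the circulating level 3 and 4 lay below every circulating library, at -1.36 to -0.20 and -1.93 to -0.86. RNA of myeloid cells, which the NKp46-GFP sort should exclude, also stays open. Of 6 CD49a+ libraries with Lyz2 in the circulating range, 2 were below every circulating one in NK receptor score. Tissue and population stay open as biological differences, since each CD49a+ group came from skin.

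Tissue residency transcripts were higher in graft CD49b+ cells than in spleen, with medians of 2.06 in B6 and 1.41 in F1. An immediate early response to tissue dissociation cannot be told apart from residency, because the 16 members outside the 7 set apart by hand had medians of 1.90 in B6 (p = 0.000198, and 0.0775 with an estimated correlation) and 0.85 in F1 (p = 0.108, and 0.431). RNA of keratinocytes or fibroblasts, which the NKp46-GFP sort should exclude, also stays open, since only 1 graft CD49b+ library had neither Krt14 nor Col1a1 and 3 were needed; 4 of 11 and 4 of 12 of these markers reached 10 in blood NK cells and 0 stand in another list. The tissue itself stays open as an untested biological difference.

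Other splits of the libraries were counted for each comparison. With 3 against 3 libraries there are 10 splits, which cannot give a share under 0.05. In B6 and F1 the real counts and the highest of the other splits were 653 and 12, and 1956 and 2 for graft CD49b+ against spleen (1 split as large in each, the real one). They were 4625 and 11, and 2524 and 17 for recipient skin against spleen (1 in each). The values were 2 and 59, and 1 and 6 for graft CD49a+ against CD49b+ (7 and 6), 36 and 865, and 4 and 131 for graft against recipient CD49a+ cells (5 in each), and 1 and 4, and 1 and 11 for spleen against blood (6 and 8). For the differences between the models chance was not excluded for graft CD49a+ against CD49b+ cells (1 gene; 38 of 100 splits as large, highest other 93) or graft against recipient CD49a+ cells (3; 72 of 100, highest other 2174). For graft CD49b+ cells against spleen the count was 0 (limma; 512 at an unadjusted p under 0.05; highest other 33), which no split can undercut, so the splits decide nothing there. The splits with many more genes than the real one point to a structure of the skin libraries that crosses groups. In B6 it went with the library number: libraries 1, 2 and 3 had 39.3, 85.0 and 43.0 percent of the circulating pan-leukocyte level in graft CD49b+, 9.09, 69.8 and 15.3 in graft CD49a+ and 11.6, 69.3 and 9.44 in recipient skin CD49a+ cells. The split with 865 genes kept both libraries 2 together, and a block for the number gave 9 genes in place of 2 for B6 graft CD49a+ against CD49b+ and 21 in place of 36 against recipient skin. The splits ignored the number, none keeping it was run, and the labels do not say what it stands for.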
